A study of Flammulina velutipes with 9 samples.

How the data were processed

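RNA from mycelium of 9 samples, 3 each of the strains JK501, JK502 and SH9, was extracted with a mirVana kit, treated with DNase and made into Illumina libraries, per the labels' protocols. The submitters' processing notes name HISAT2 2.0.4 and Cufflinks 2.1.1. The role of each tool, the genome build, the annotation, the counting tool and its strand setting are not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical copies therefore cannot be told apart, and the counts of such genes are uncertain. A difference in sequence between a strain and the reference can also lower the counts of a gene in that strain.

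The deposited table holds whole-number counts per gene, not normalized, and FPKM values for 10727 genes in all libraries, per the file headers. The authors' FPKM equalled the count divided by a fixed whole-number gene length and by the summed gene counts of the library, as found from the values. Lengths could be recovered for the 8675 genes with a count in any library, with a median of 1122 bases. As 99.9% of them are multiples of 3, they are called coding lengths. FPKM values are therefore scaled by library totals, while the tests used a further scaling. No sample column was left out. Genes carry only running numbers and no genome was used here, so positions, names and GC content are not given.

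Tests ran on the counts. A test with limma on log2(FPKM + 1) had been planned before the data were examined, with edgeR as the stated choice if counts were deposited. Since they were, edgeR 4.0.16 in R 4.3.3 gave the main results, and the limma fit planned as the main test was kept as an alternative, a role it was given after the data were seen. Genes were kept by edgeR's filterByExpr, which left 8088. Libraries were scaled by TMM, whose factors were 0.897 to 0.920 in JK501, 0.916 to 1.04 in JK502 and 1.11 to 1.19 in SH9. One quasi-likelihood model with 9 libraries and no covariate gave all comparisons, two-sided, with Benjamini-Hochberg adjustment within each comparison and calls at an adjusted p under 0.05. SEs of log2 fold changes come from the variance of log2 CPM between the libraries of each strain, not from the model. Principal components and correlations used log2 CPM with a prior count of 0.5.

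Genes were named by a rule set before the data were examined. Among called genes whose libraries did not overlap and whose mean was at least 5 FPKM in the higher strain, the 2 with the largest rise and the 2 with the largest fall in each comparison were taken. Genes that passed this rule before the choice of the largest changes numbered 1372 higher and 1256 lower in JK501 than in SH9, 1404 and 1013 in JK502 than in SH9, and 85 and 69 in JK502 than in JK501. Some genes near 0 in a strain are named besides these, each said to be chosen after its values were seen. For genes with 1 to 3 counts in a strain, the ratio of summed counts scaled for library size is given with an exact counting interval at 95%, in place of the fitted fold change. Replicates were compared before use: the chi-square per degree of freedom of their counts was 36.3 to 199, far above sampling noise, so no library appeared to be deposited more than once.

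The total gene counts were 16319471, 17287306 and 15570084 in JK501 replicates 1, 2 and 3, 17195316, 15812202 and 16779076 in JK502, and 15583684, 15355058 and 14563976 in SH9. The common biological coefficient of variation was 24.3%. The test was tried on simulated counts for the 8088 genes with 200 genes changed by known amounts. For JK501 against SH9, edgeR recovered 30% of the genes changed 2-fold and 93% of those changed 4-fold, with 4 false calls. For JK502 against SH9 these were 40% and 92% with 9 false calls, and for JK502 against JK501 34% and 92% with 7. DESeq2 1.42.0 recovered 58%, 62% and 54% of the 2-fold changes in the same order, with 18, 36 and 24 false calls. Its higher recovery thus came with more false calls than edgeR's in each comparison. Against SH9, 2905 genes were called in JK501 and 2779 in JK502, far more than the 200 changed here. With more changed genes the adjusted threshold is easier to pass. Recovery at such numbers was not simulated, so how often changes near 2-fold are missed against SH9 is not known. Between JK502 and JK501, with 168 called genes, a lack of a call is weak evidence for changes near 2-fold.

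Alternatives were other scalings (median ratio, library totals, quantile), no filter or a filter of at least 5 FPKM in 3 or more libraries, limma 3.58.1 with a pseudocount of 1 or 0.1 and with or without a variance trend, DESeq2, a model of only the groups compared, a minimum change of 2-fold, the replicate number as a block and each library left out in turn. Shared controls were simulated 40 times as unchanged groups, with the lists taken both by the threshold and by rank at the sizes called in the data. The lists by rank were added after the data were seen. The comparison of single values used an exact permutation test, which with 3 against 3 libraries cannot give a p under 0.1.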

Results

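Gene expression was measured by RNA sequencing in mycelium, the thread-like vegetative growth that precedes fruiting, of Flammulina velutipes, the edible enoki or golden needle mushroom. Mycelium of 3 strains was harvested after 10 days on PDA medium at 25 °C. JK501 and JK502 are selected strains and SH9 is their parent, and the labels give early fruiting as the phenotype of JK501 and anti-disease as that of JK502. Each strain had 3 libraries. The labels do not say whether these came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Counts were given for 10727 genes, and the total gene count per library lay between 14563976 and 17287306. Of these genes, 2052 had a count of 0 in all 9 libraries and 8088 entered the tests. The genes carry running numbers that the deposited table does not pair with names, so no gene can be tied to a function, none of 20 gene lists written before the data were examined could be tested, and the rule for naming genes took at most 2 per direction in each comparison.

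The libraries separated by strain. The first principal component of log2 CPM held 56.6% of the variance and set SH9, at 41.9 to 66.4, apart from JK501, at -28.0 to -22.6, and JK502, at -41.8 to -12.8. The second component held 14.3% and set JK501 apart from JK502. Across genes, which are not independent replicates, log2 CPM of JK501 and JK502 libraries correlated at r = 0.955 to 0.966, while SH9 libraries correlated at 0.906 to 0.936 with JK501 and at 0.874 to 0.939 with JK502. Within strains r lay between 0.963 and 0.985. On the first component JK502 replicate 1, at -12.8, and SH9 replicate 3, at 41.9, each lay nearer to the opposite side than the others of their strain. The biological coefficient of variation was 18.9% in JK501, 23.2% in SH9 and 29.5% in JK502.

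**Figure D1:**
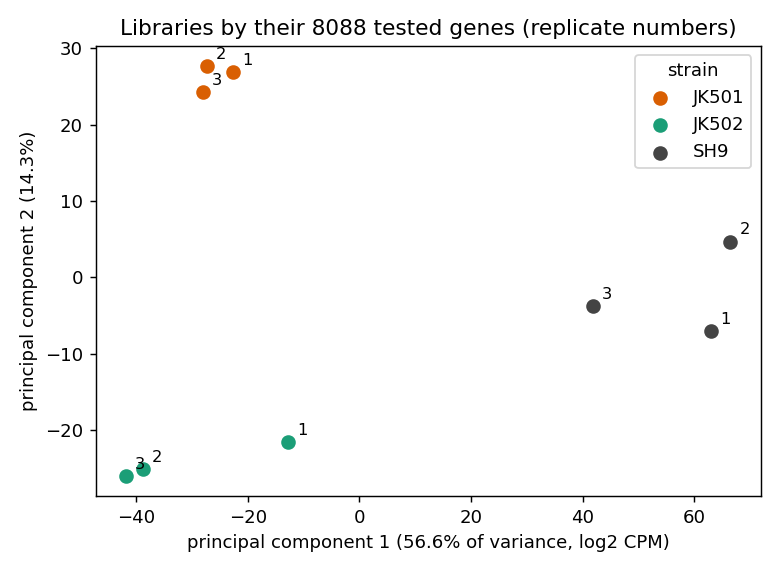
Principal components of log2 CPM over the 8088 tested genes, with one point per library, its replicate number beside it and the strain as colour. The first component (56.6% of the variance) sets the 3 SH9 libraries, at 41.9 to 66.4, apart from the selected strains, and the second (14.3%) sets JK501 apart from JK502.

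JK501 was compared with SH9 to ask how the mycelium of the early fruiting strain differed from that of its parent. Gene g483, with a coding length of 555 bases, was at 43.0 ± 23.1 FPKM in JK501 and 0.712 ± 0.308 in SH9 (SD, n = 3 each), a log2 fold change of 6.22 ± 0.58 (SE). Gene g6202 (1146 bases) stood at 524 ± 263 FPKM in JK501 against 19.7 ± 13.2 in SH9, which made it 5.08 ± 0.69 higher on the log2 scale. In the other direction, g9507 (534 bases) fell from 2405 ± 1697 FPKM in SH9 to 16.4 ± 16.1 in JK501, a log2 fold change of -6.87 ± 1.24. Gene g8075 (864 bases) fell from 39.7 ± 31.1 to 0.117 ± 0.104 FPKM, where the JK501 value rests on 5 counts over the 3 libraries and the log2 fold change was -7.98 ± 1.44. The adjusted p of edgeR's quasi-likelihood test was 0.000178 for g483, 0.00117 for g6202, 0.00152 for g9507 and 0.00104 for g8075. In each of these genes the 3 libraries of one strain lay above the 3 of the other. Both a call and this separation were conditions of the naming rule, so neither is further evidence. Leaving out single libraries put the log2 fold change of g6202 between 4.57 (without JK501 replicate 2) and 5.77 (without SH9 replicate 3). The same step put g9507 between -8.04 (without JK501 replicate 1) and -6.41 (without SH9 replicate 2), and g8075 between -8.61 (without JK501 replicate 2) and -7.34 (without SH9 replicate 2).

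Of the 8088 genes, 1432 were higher and 1473 lower in JK501 than in SH9 at an adjusted p under 0.05, together 35.9%. The change was at least 2-fold for 628 of the higher and 861 of the lower genes, and at least 8-fold for 54 and 79. The median log2 fold change was 0.94 among the higher and -1.12 among the lower genes. All libraries of one strain lay above all of the other for 2848 of the 2905 called genes and for 55.9% of all tested genes, where chance gives 10%. With the libraries scaled by their totals alone, a setting added after the data were seen, the median log2 fold change of all genes moved from -0.03 to -0.36, and the share of higher genes among the calls from 49.3% to 21.3% (740 higher, 2734 lower), and limma on FPKM, scaled in the same way, called 752 and 2692. Without SH9 replicate 1 the counts were 880 and 888, and the lower genes numbered 899 without JK501 replicate 2 and 900 without JK501 replicate 3.

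JK502 was compared with SH9 to ask the same of the strain labelled anti-disease. Gene g6202 was again among the highest risers, at 2068 ± 1565 FPKM in JK502 (SD, n = 3) and a log2 fold change of 7.01 ± 0.84 (SE). Gene g10607 (1113 bases) rose from 0.961 ± 0.839 FPKM in SH9 to 109 ± 98.8 in JK502, a log2 fold change of 7.10 ± 1.24. Gene g259 (942 bases) was at 175 ± 36.6 FPKM in SH9 and 0.0646 ± 0.0633 in JK502, where it had 3 counts in all. Its counts, scaled for library size, were 2299 times higher in SH9, with a 95% counting interval of 787 to 11152. Gene g3288 (2589 bases) had 1 count in JK502 and 1160 in SH9, at 9.75 ± 4.06 FPKM in SH9, a ratio of 1064 with a counting interval of 191 to 42070. These intervals cover counting error only. With single libraries left out the ratio of g259 lay between 1437 (without JK502 replicate 1) and 4683 (without JK502 replicate 3). That of g3288 lay between 665 (without JK502 replicate 1) and 1302 (without SH9 replicate 3), and without JK502 replicate 3, which held its only count, g3288 was at least 241-fold lower in JK502, at a floor of 3 counts over the group. The edgeR adjusted p was 0.000564 for g6202, 0.00132 for g10607 and 0.000123 for both g259 and g3288. The libraries of JK502 and SH9 did not overlap in any of these genes, as the naming rule required. Leaving out single libraries put g6202 between 6.12 and 7.70, and g10607 between 5.98 and 7.96, on the log2 scale. The lowest value came without JK502 replicate 3 in both genes, and the highest without SH9 replicate 3 for g6202 and without SH9 replicate 1 for g10607.

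Genes g259 and g3288 belonged to a group of 8 genes that had at most 3 counts over the JK502 libraries and at least 20 counts in every SH9 library, a group defined after the data were seen. Together these genes had 4 counts in JK502 and 9941 in SH9, where 9120 would have been found in JK502 at the level of SH9. The smallest count expected for any of them was 58.7. Their mean level in SH9 ran from 0.961 to 175 FPKM, and 6 of them had a count of 0 in all JK502 libraries. All 8 were called lower in JK502, which the definition of the group makes nearly certain. In JK501 the same genes had 3626 counts, of which 2400 were from g259 and 755 from g3288. Their log2 fold changes in JK501 against SH9 lay between -3.08 and 0.00. There 4 of the 8 were called lower too, as were 1473 of all 8088 tested genes. The genes were chosen partly by their counts in the same SH9 libraries, which can by itself favour lower values in JK501. In JK501, by the same criterion, 1 gene was near 0 and counted in SH9, g6313, with 0 counts in JK501, 30 in JK502 and 191 in SH9. It was named after its values were seen. No gene was near 0 in SH9 and counted in every library of a selected strain.

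In total 1508 genes were higher and 1271 lower in JK502 than in SH9, 34.4% of those tested, by edgeR at an adjusted p under 0.05. At least 2-fold changes were found for 737 higher and 708 lower genes, and at least 8-fold changes for 85 and 70. The median log2 fold change was 0.98 among the higher and -1.08 among the lower genes. The libraries of both strains did not overlap for 2623 of the 2779 called genes and for 45.4% of all tested genes, against 10% by chance. Scaled by library totals alone, the median of all genes moved from -0.02 to -0.27 and the share of higher genes among the calls from 54.3% to 29.9% (924 higher, 2169 lower), and limma on FPKM called 929 and 2297. The counts were 893 and 676 without SH9 replicate 1 and 859 and 678 without SH9 replicate 2, and the lower genes numbered 750 without JK502 replicate 2 and 771 without JK502 replicate 3.

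Both selected strains differed from SH9 in many of the same genes. Gene g483 was at 47.3 ± 3.51 FPKM in JK502 (SD, n = 3), a log2 fold change of 6.28 ± 0.35 against SH9 (edgeR adjusted p = 0.000123). In JK502, g9507 was at 7.49 ± 5.65 FPKM and g8075 at 0.188 ± 0.108 FPKM, with log2 fold changes of -8.04 ± 1.17 and -7.41 ± 1.25 (edgeR adjusted p = 0.00132 for each). Higher in both strains were 974 genes, 68.0% of those higher in JK501 and 64.6% of those higher in JK502. Lower in both were 905 genes, 61.4% and 71.2% of the respective lists. Independent lists of these sizes would share 267 higher and 231 lower genes. Of the 3798 genes called in either comparison, 95.3% had the same sign in both, and 7 genes were called in opposite directions. In simulations where no gene changed, lists of the sizes called had 75.2% with the same sign. Across genes, the log2 fold changes of both strains correlated at r = 0.828 with a covariance of 0.838.

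Both comparisons used the same SH9 libraries, which alone produces a correlation. In 40 simulations of unchanged groups against these controls, r averaged 0.496 and the covariance 0.0505. No gene was called in both comparisons there, so lists of the sizes called in the data were also taken by the smallest p. These shared 1190 genes in the same direction on average and at most 1236, against the 1879 observed, and 75.2% of the genes in either list had the same sign, at most 76.7%. The difference of the covariances was 0.788. No gene was changed in these simulations, so their list values are no baseline for lists that hold changed genes. Each gene was also drawn independently, while many genes of a real library can shift together. The highest simulated values may therefore be too low for what shared controls can produce. With 3 libraries SH9 cannot be split into parts of at least 2, so part of the excess in shared calls may come from the shared controls. The genes called in the same direction in both strains numbered 1879, against 1011 without SH9 replicate 1 and 1024 without SH9 replicate 2.

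**Figure D2:**
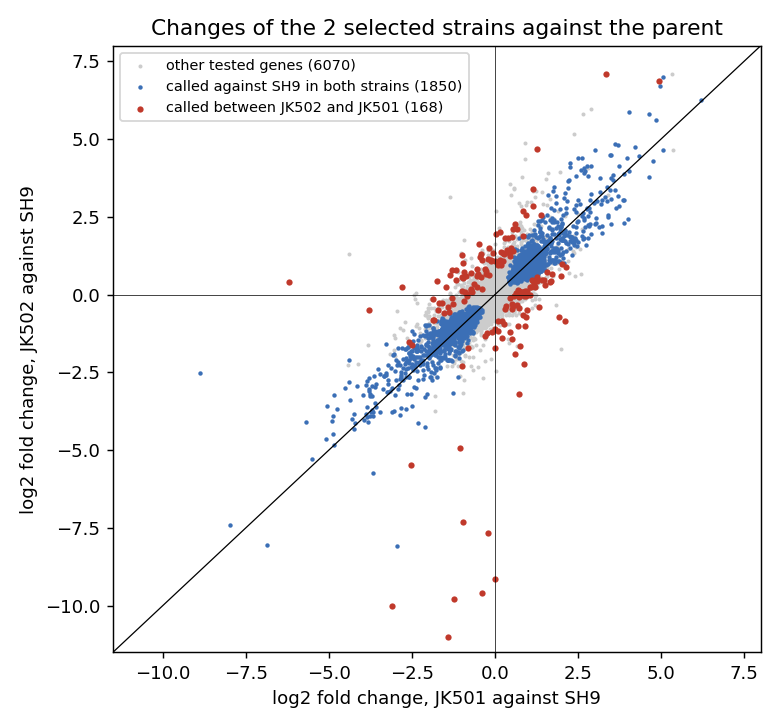
Log2 fold change of each tested gene against SH9, JK501 on the horizontal and JK502 on the vertical axis, with the line of equal change. Blue points are genes called against SH9 in both strains and not between the strains, red points the 168 genes called between JK502 and JK501, and grey points the other genes; the correlation across genes was 0.828, and the points near the bottom include g259 and g3288, whose fitted values rest on 3 counts and 1 count in JK502.

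JK502 and JK501 were compared directly to ask in which genes the selected strains differed from each other. Gene g10607 was at 7.84 ± 5.27 FPKM in JK501 and 109 ± 98.8 in JK502 (SD, n = 3 each), a log2 fold change of 3.75 ± 0.98 (SE). Gene g6361 (705 bases) was at 1.15 ± 0.673 FPKM in JK501, 9.98 ± 3.63 in JK502 and 10.1 ± 1.71 in SH9. It was thus 3.02 ± 0.54 higher in JK502 than in JK501 on the log2 scale, and its log2 fold change in JK501 against SH9 was -2.79 ± 0.46. Gene g259 was at 53.2 ± 41.7 FPKM in JK501, 854 times its level in JK502 by scaled counts (counting interval 292 to 4146). Gene g3288 was at 5.91 ± 1.74 FPKM in JK501, and its ratio to JK502 was 806 (144 to 31893). Leaving out single libraries put the ratio of g259 between 489 (without JK501 replicate 3) and 1740 (without JK502 replicate 3) and that of g3288 between 504 (without JK502 replicate 1) and 917 (without JK501 replicate 3), or at least 182-fold without JK502 replicate 3. The adjusted p of edgeR's test between the strains was 0.0440 for g10607, 0.00952 for g6361, 0.0016 for g259 and 0.00104 for g3288. For g10607 the call was lost without JK502 replicate 3, where the log2 fold change was 2.62, and without any of JK501 replicates 1, 2 and 3 (3.46, 3.53 and 4.43) or SH9 replicates 1 and 3 (3.75 in both cases), and also with only the compared strains in the model (3.75) or in limma with a pseudocount of 0.1 (3.52). For g6361 it was lost without JK501 replicate 2, at a log2 fold change of 2.87. Gene g6202, with 524 ± 263 FPKM in JK501 and 2068 ± 1565 in JK502, did not pass between the strains (log2 fold change 1.93 ± 0.73, edgeR adjusted p = 0.135).

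Between the strains 168 genes were called, 2.08% of those tested, 89 higher and 79 lower in JK502. The change was at least 2-fold for 63 and 44 of them. The median log2 fold change was 1.20 among the higher and -1.04 among the lower genes. In all 168 the libraries of JK501 and JK502 did not overlap, as in 23.8% of all tested genes, against 10% by chance. Of the 168 genes, 66 were called against SH9 in JK501 alone, 62 in JK502 alone and 36 in both strains, and in 82 JK501 lay closer to SH9. Scaling by library totals moved the median of all genes from 0.04 to 0.11 and the share of higher genes among the calls from 53.0% to 65.1%. DESeq2 called 334 higher and 315 lower genes, and a model of only these strains 23 and 27. The number of calls depended on single libraries: the higher and lower genes numbered 11 and 21, 10 and 13, and 11 and 13 without JK501 replicates 1, 2 and 3, then 204 and 167, 51 and 45, and 56 and 42 without JK502 replicates 1, 2 and 3, while 41 were higher without SH9 replicate 1.

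**Figure D3:**
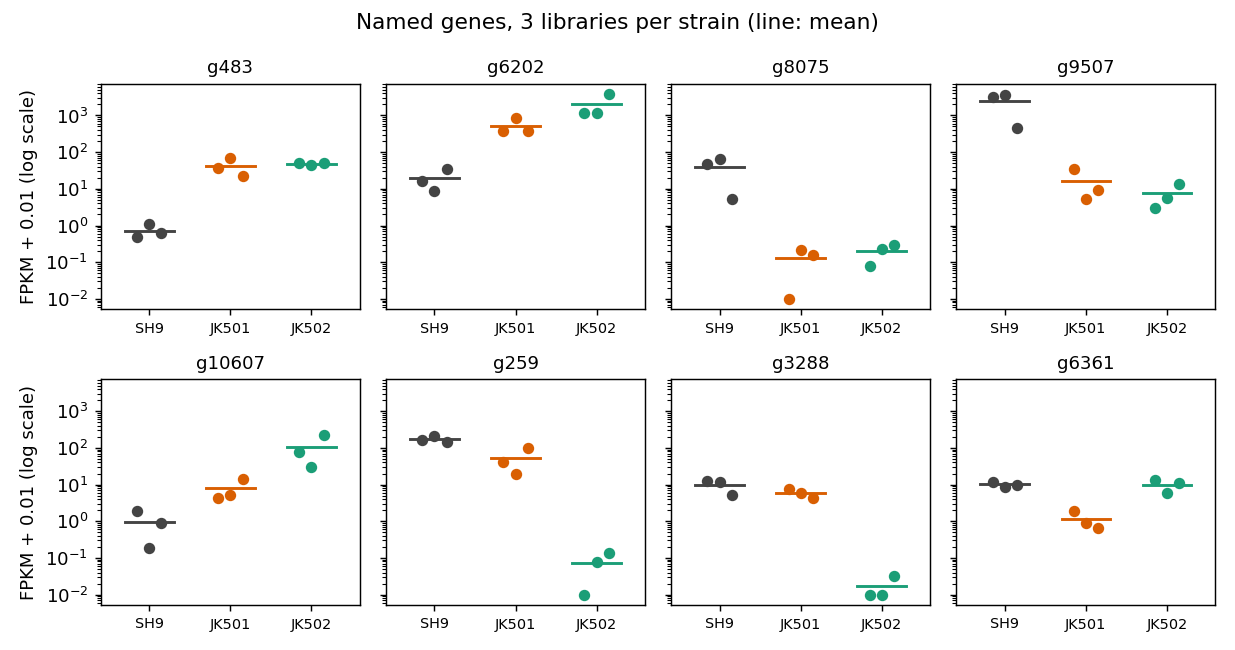
FPKM of the 8 genes named by rule in each library on a log scale, after adding 0.01 so that libraries at 0 can be drawn, with one point per library and a line at the mean of the 3 libraries. Genes g483 and g6202 lie higher and g8075 and g9507 lower in both selected strains than in SH9, while g259 and g3288 lie near 0 in JK502 alone and g6361 is lowest in JK501.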

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

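The tests of abundant genes, of a level-dependent difference, of the genes near 0 and of mixed libraries were chosen only after the results were seen. The limits of the mixed-library tests were also revised after a first result, and the depth test replaced one whose outcome was fixed by how the genes near 0 were defined. The tests with a length trend and over other splits of the libraries were set beforehand.

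The changes of the selected strains against SH9 differed from each other in 3 of the genes named against SH9. Since SH9 drops out of this difference, edgeR's test of it is the direct comparison of JK502 with JK501 given above, not a further test. For g10607 the difference of the log2 fold changes, JK502 minus JK501, was 3.75 (adjusted p = 0.0440), and this call was lost in 8 refits, among them each one without a JK501 library. For g259 the fitted difference was -9.60 (adjusted p = 0.0016) and for g3288 -9.19 (adjusted p = 0.00104), both of which depend on the 3 counts and 1 count of these genes in JK502. Another 7 genes were called in opposite directions against SH9 in JK501 and JK502. All of them were called between the strains, which changes in opposite directions make likely.

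Many genes differed between each selected strain and SH9. Scaled by library totals, since TMM already trims abundant genes, removal of the 50 most abundant genes moved the median of all genes from -0.36 to -0.21 in JK501 and from -0.27 to -0.20 in JK502 and kept 79.7% and 88.6% of the calls, short of the 90% written down for TMM scaling; 959 higher and 2030 lower genes were still called in JK501 and 1025 and 1815 in JK502, so by a criterion added afterwards these genes are not the whole cause, though part of the shift goes with them. With a length trend per library 97.8% of the calls were kept in JK501 and 96.7% in JK502, which argues against a length bias as the whole cause. Cyclic loess, which removes any trend with gene level, was run with limma and kept 78.4% of the calls in JK501, below the 80% written down before it was run, and 81.9% in JK502; it still called 1382 higher and 1350 lower genes in JK501 and 1371 and 1291 in JK502, so by the same criterion a level trend is not the whole cause. The labels give no culture or library batch, so a shared difference in how the SH9 samples were grown or handled cannot be told apart from a difference between strains, and the biological explanation, selection of the strains, stays open as well.

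Other splits of the libraries are too few to give a share under 0.05. Each of them also mixes both strains in both groups, so a difference between strains widens the spread within groups. Few or no calls there are thus nearly assured, whatever the cause of the difference. Of the 10 splits of the 6 libraries in each comparison, only 1, the real one, gave as many genes. The real splits called 2905 genes in JK501 against SH9, 2779 in JK502 against SH9 and 168 in JK502 against JK501, and the highest of the other splits called 0 in each by edgeR. At an unadjusted p under 0.05 the highest of the other splits reached 462, 1758 and 1091 genes, where the real ones had 3831, 3819 and 1574. DESeq2 was not run on the splits.

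A lower depth of JK502 is argued against for the group of 8 genes near 0 there, since its libraries had 91.7% of the scaled depth of those of SH9. Loss of a long stretch is argued against only where their neighbours by number entered the tests. Of the 8 tested neighbours, 0% were at least 8-fold lower (median log2 fold change -0.03, range -0.95 to 1.41). The other neighbours did not enter the tests. Around g259 no other gene between g246 and g271 did, so a long loss there could not have been seen. The argument also holds only if the numbers follow the order in the genome, which is not given in the sources used here. A short loss that takes in the adjacent g2129 and g2130, named after their values were seen, stays open. A deletion of single genes, silencing, or sequence variants that keep reads of JK502 from being counted may each produce such values and were not tested. In JK501 the genes had a median log2 fold change of -1.10 against SH9, which their choice by SH9 counts may have lowered.

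JK502 replicate 1 and SH9 replicate 3 lay between the parent and the selected strains on the first principal component. Parent RNA mixed into JK502 replicate 1 would have to make up a median of 34.8% (95% bootstrap interval 28.3 to 42.4) over 325 genes that differ strongly. The 6 genes at 0 in the other JK502 libraries had 0 counts there where 432 would come from pure parent RNA, which allows a share of up to 0.854%. For SH9 replicate 3 the shift needed 15.5% (13.6 to 18.7) over 292 genes, while 11 genes nearly silent in the other SH9 libraries gave a median of 2.20% (0.564 to 5.20). The genes were picked for a large gap in which the library in question was not on its own side, which can by itself raise the share it seems to need. Shares needed by single genes spread widely, with quartiles of 4.55% and 59.3% for JK502 replicate 1 and 3.73% and 42.2% for SH9 replicate 3. Mixed parent RNA is argued against as the whole cause in JK502 replicate 1. In SH9 replicate 3 the interval of the needed median, from 13.6%, lies above that of the nearly silent genes, which ends at 5.20%. Over these genes this argues against mixed RNA as the whole cause there. A mixed share within the latter interval stays open. Differences in the growth state of the cultures or in handling stay open, as no value here tests them.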

How the results depend on the processing

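Of the alternatives, limma on log2(FPKM + 1), which had been planned as the main test, became one only once counts were found, and library totals only, both apart-lying libraries left out together and other limits for the genes near 0 were added after the data were seen. Counts of calls, the overlap, the correlation and the genes near 0 were recomputed under those alternatives that apply to each; the genes near 0, which rest on no test, only with other limits and with libraries left out, the overlap and the correlation not with only the groups compared, and the correlation not with a fold minimum. Of these values, 126 stayed within 1.5 times the main count, or within the leave-one-out error of the correlation, and 58 did not. Refits of the named genes numbered 264, of which 255 kept direction and call and 9 lost the call, 8 of them for g10607 and 1 for g6361 between the strains; no direction turned. For g10607 between the strains the adjusted p reached 0.162 without JK501 replicate 1.

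Scaling by library totals gave 740 higher and 2734 lower genes in JK501 than in SH9, 924 and 2169 in JK502 than in SH9, and 51 lower in JK502 than in JK501. The limma fits, on values scaled in the same way, gave 752 and 2692 in JK501 and 929 and 2297 in JK502 with a pseudocount of 1, 749 and 2641, and 923 and 2244, with 0.1, and without a trend 726 and 2688, 889 and 2299, and 48 lower between the strains. The shift of all genes seen with library totals (medians of -0.36 and -0.27) goes with these splits. A minimum change of 2-fold left 628 and 861, 737 and 708, and 44 lower between the strains, and 937 shared genes, by construction. Between the strains, only the groups compared in the model gave 23 and 27 and DESeq2 334 and 315, and the cause was not tested. In the simulations DESeq2 recovered more of the 2-fold changes than edgeR but also made more false calls. Without both JK502 replicate 1 and SH9 replicate 3 there were 243 and 179. These libraries were chosen because they lay apart from their strains, so more calls can follow from that choice alone. The last setting gave 1713 and 1848 in JK501 against SH9 and 1966 and 1906 in JK502 against SH9. The correlation was 0.868 with quantile normalization and 0.783 with no filter, where genes of few counts enter. With at least 50 counts in every SH9 library 5 genes were near 0 in JK502: g259, g2129, g2130, g3175 and g3288, named after their values were seen.

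With single libraries left out, the higher genes ran from 880 to 1638 and the lower from 888 to 1713 in JK501 against SH9, from 859 to 1900 and from 676 to 1780 in JK502 against SH9, and from 10 to 204 and from 13 to 167 in JK502 against JK501. Shared genes ran from 1011 to 2386, the correlation from 0.802 to 0.850 and the genes near 0 from 8 to 9. Fewer libraries lower the power, but without JK502 replicate 1 the counts rose to 1900 and 1780 against SH9 and to 204 and 167 between the strains.

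The labels tie no samples together by replicate number, so the samples were treated as unpaired. The correlations of the deviations of same-numbered libraries, -0.06 to 0.27, were above 0.1 in 5 of 9 pairs. Only that of JK502 replicate 2 with SH9 replicate 2 was below 0. As a further hint from the data that some numbers may share something, 4 of 9 libraries correlated best with their own number in both other strains. How many would do so without any link was not determined. The replicate block gave 1451 higher and 1530 lower genes in JK501 against SH9, 1511 and 1369 in JK502 against SH9, and 99 and 75 between the strains. Alternatives for gene lists were not run, since no list could be matched. With a spread of 24.3% and 3 libraries, changes near 2-fold were often missed in simulations with 200 changed genes. Against SH9, where many more genes were called, the share missed was not simulated. Below about 3 counts per strain a fold change is limited by depth.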

Other observations

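The run counts given here were tested only after the runs were seen, and the classes by abundance and length were also set after the data were seen.

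Called genes were spread unevenly over levels of abundance, and how evenly depends on the level used to class them. Classes by the mean over all libraries are moved by the change itself, upward by genes that rose in both selected strains, and classes by the level in SH9 are moved the opposite way. Classes by the mean log2 level of only the strains compared treat both strains alike. Relative to SH9, however, a rise still moves a gene up and a fall of the same size moves it down as far. In these classes the 1402 genes at 100 to 1000 FPKM held 402 higher and 135 lower genes in JK501 against SH9, by edgeR at an adjusted p under 0.05. The 1405 such genes in JK502 held 425 and 124. Their medians lay 0.23 and 0.27 above that of all genes on the log2 scale. At 1 to 10 FPKM, 144 genes were higher and 531 lower in JK501, and 187 and 437 in JK502, with medians that differed from that of all genes by -0.35 and -0.30. With library totals alone the class at 100 to 1000 FPKM had 226 higher and 352 lower genes in JK501 and 262 and 264 in JK502, so its lean holds only relative to the other genes.

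Classed by the level in SH9 instead, the lean was smaller and did not hold at both ends. At 100 to 1000 FPKM 349 genes were higher and 240 lower in JK501, and 372 and 203 in JK502, and at 1 to 10 FPKM 194 and 341, and 250 and 298. Over 1000 FPKM in SH9, 14 genes were higher and 27 lower in JK501 and 24 and 19 in JK502, and under 1 FPKM 19 and 9, and 27 and 10. The 10 most abundant genes of each library took 11.0% ± 0.562 of all counts in JK501, 8.92% ± 0.652 in JK502 and 7.28% ± 0.440 in SH9 (SD, n = 3), and each selected strain against SH9 gave an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. Genes at 0 numbered 2264.7 ± 21.6 per library in SH9, 2333.7 ± 4.04 in JK501 and 2324 ± 12.5 in JK502 (SD, n = 3), a difference that was not tested.

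Fold changes also differed with coding length. In JK502 against SH9 the median log2 fold change was 0.10 among genes of up to 768 bases and -0.13 among those of 1779 bases or more (Spearman's rho across genes -0.12). In JK502 against JK501 these medians were 0.13 and -0.08 (rho -0.18), and in JK501 against SH9 -0.02 and -0.04 (rho -0.03). With a length trend per library in the model, 101 genes were higher and 107 lower in JK502 than in JK501, against 89 and 79 without it.

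Runs of consecutively numbered genes called in the same direction were more frequent than in a shuffled order of all genes, tested or not, although they held few of the called genes. Untested genes stood partly in stretches, as between g246 and g259, and shuffling spread these out. It thus also broke up blocks of tested genes, which by itself lowers the number of runs. The excess of runs therefore cannot tell by itself whether neighbours change together. Runs of 4 or more such genes numbered 21 in JK501 against SH9, where 1000 shufflings of the gene order gave a median of 6 and at most 15, and 26 in JK502 against SH9, where they gave a median of 5 and at most 14. The runs held 91 of the 2905 and 105 of the 2779 called genes, 11 runs up and 10 down in JK501 and 17 up and 9 down in JK502. JK502 against JK501, with 168 called genes, had 0 runs by edgeR, as in every shuffling. Log2 fold changes of direct neighbours by number correlated weakly, at r = 0.099 in JK501 against SH9, 0.097 in JK502 against SH9 and 0.0998 between the strains, where shuffling reached at most 0.037, 0.043 and 0.053. For the next but one the values were 0.015, 0.008 and -0.016. A hypothesis is that the numbers follow the genome and that some neighbouring genes, such as gene clusters, change together; reads shared by overlapping neighbours or by tandem copies may give the same runs and were not tested, as no positions or sequences were used here.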
